A study of Mus musculus with 7 samples.

How the data were processed

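Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in 2 mouse striatal cell lines, STHdhQ7 and STHdhQ111, called Q7 and Q111 from here on. The labels list 7 samples: FRA2, JUND and IgG in each line, and SOX2 in Q7. Each sample title states that replicates 1 and 2 were pooled, so every group holds 1 value, no spread between replicates can be computed, and no fit pairs or leaves out replicates. Groups were taken from the sample titles. Per the submitters' processing notes the aligner was Bowtie 0.12.7 and the genome build mm9. The name of the GPS event caller appears with the deposited tables, and its version and settings are not given in the sources used here.

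The deposited tables hold 1 line per binding event, a single base position on mm9. FRA2 and JUND each have a table that covers both lines, and SOX2 has a table for Q7. The IP columns hold expected counts, per the file headers and the deposited values: reads assigned to the event and not scaled, with between 78.0% and 89.6% of values whole and the remainder fractional. They were rounded to whole reads for the tests. The Control columns hold a signal, per the file headers: control reads multiplied by a factor per library, judged from steps of 1.0 to 1.2 between low deposited values. The headers do not say which library served as control, and IgG is the only control antibody in the labels. No separate IgG table was used here. The deposited ratio of IP to control reads (Fold), the deposited p-value and the q-value (both as −log10) and a present mark for each line complete the tables. The deposited p-value was matched within 0.03 by a binomial comparison of IP with control reads for 79.3% to 92.8% of events, depending on the library. There were 10 further value columns that were not used here.

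Reads in events, the only depth the tables give, came to 3340554 for FRA2 in Q7, 3498922 for FRA2 in Q111, 1660158 for JUND in Q7, 1609483 for JUND in Q111 and 1193914 for SOX2 in Q7. These are sums over listed events, not library sizes. At this depth the median event held 27 to 33 reads per library.

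Q111 was compared with Q7 event by event with a two-sided exact binomial test of the Q111 share of reads. The expected share came from the median log2 ratio (Q111 over Q7) over events marked present in both lines, which was 0.05 for FRA2 and 0.07 for JUND. P-values were adjusted by the Benjamini-Hochberg method over events with at least 20 reads, which all listed events had. An event was called different with an adjusted p below 0.05 and a fold of at least 2, computed with a pseudocount of 0.5 reads. Intervals of folds are 95% Clopper-Pearson intervals of the read share, intervals of percentages are Wilson intervals, and intervals of medians come from 1000 bootstrap draws of events. They cover counting error or the sampling of events only: PCR reads are not independent molecules, and the tests compare pairs of pooled libraries, not the genotypes. Because the bootstrap draws single events, its intervals are too narrow where folds of neighbouring events move together. Where an event rounded to 0 reads in a line, the fold is a lower bound computed against a floor of 3 reads, close to the one-sided 95% limit for a count of 0, so the two-sided interval starts lower.

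Events of different tables were matched by distance, with 100 bp as the limit for a shared event, and the matched share was set beside 100 random displacements of 10 to 100 kb. Such displacements take events off their sites, so they do not show what share unrelated proteins would have. FRA2 and JUND events were paired where each was the other's nearest. Their fold differences were compared by a two-sided exact hypergeometric test on the 4 read numbers, adjusted as above. FRA2 and JUND events within 1 kb of a SOX2 event were compared with the remaining events by the difference of median log2 folds, beside 10000 random event sets matched on reads in 10 bins. No p-value was computed across events, which are not replicates.

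Apart from the additions named below, the tests, groups, thresholds, alternatives and the rule for named events were fixed before the data were examined. The rule takes, for FRA2 and for JUND, the 10 called events per direction whose fold interval lies farthest from 1, the 5 events with the most reads, the 10 SOX2 events with the most reads, and the 5 shared events per direction with the farthest intervals in both tables. It was written for genes and applied to positions, because no annotation of mm9 was used here. For the same reason the planned gene lists, the genomic location of events and the search for motifs were not run, and the only gene table at hand was of another build. The alternatives changed the scaling, the read minimum, the q-value limit, the fold limit, the distance limits and the assumed spread. The test of the FRA2 against the JUND difference at each pair, merging of adjacent events, removal of events with 40 or more control reads, use of the Q7 control for both lines, comparison within bins of Q7 reads, the tests of library yield, replacement lists and control reads by chromosome among called events, the windows of 5 Mb with their shuffles, and restriction of chromosome shifts to events present in both lines were added after seeing the data.

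The test was tried on simulated reads with 200 changed events, drawn with counting error alone. For FRA2 it recovered 18% of events changed 2-fold, which lie at the fold limit, and 78% of those changed 4-fold, with 6 false calls among 64579 events. For JUND it recovered 14% and 63%, with 5 false calls among 46583 events. The simulation holds no spread between libraries, so the false calls do not measure it. Far fewer events were changed than were called in the data, which makes the adjustment stricter. The recovered shares are therefore not those of the real comparison. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1.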

Results

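FRA2 and JUND, subunits of the dimeric transcription factor AP-1, and SOX2, a transcription factor of neural progenitors, were mapped by ChIP-seq in immortalised striatal cells derived from mouse embryos at day 14. The Q7 line is homozygous for huntingtin with a short glutamine tract, and the Q111 line is homozygous for a tract expanded into the range that causes Huntington's disease. Cells of fewer than 15 passages were kept at 33 °C and moved to 39 °C for 2 days before the experiment to stop division. FRA2 and JUND were measured in both lines, 1 pooled sample each, and SOX2 in Q7. There were 64579 FRA2 events, 46583 JUND events and 26433 SOX2 events, with 3340554 FRA2 reads in Q7, 3498922 FRA2 reads in Q111, 1660158 JUND reads in Q7, 1609483 JUND reads in Q111 and 1193914 SOX2 reads. Without separate replicates, all differences below are between pooled libraries.

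The first comparison asked where FRA2 binding differs between the lines. FRA2 reads were higher in Q111 at 15042 events (23.3%, Wilson interval 23.0 to 23.6%) and higher in Q7 at 13755 events (21.3%, 21.0 to 21.6%), while 35782 events (55.4%) were not called. The median event called higher in Q111 differed 3.55-fold, and the median event called higher in Q7 differed 3.36-fold. A difference of at least 4-fold was reached by 6302 of the events higher in Q111 and by 5158 of those higher in Q7. Called events held a median of 55 (higher in Q111) and 53 (higher in Q7) reads over both lines, against 73 reads for events not called. Of the events higher in Q111 22.0%, and of those higher in Q7 23.3%, were marked present in both lines. Of the 30731 events present in both lines, 78.8% were not called. All listed events were marked present in at least 1 line, so the called share is not that of all FRA2 sites.

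Among the FRA2 events with the most extreme intervals, 3 of the 10 higher in Q111 lay on chromosome 11 between positions 106815657 and 111758502. The event at chromosome 11 position 106815657 had 157 reads in Q111 and 0 in Q7, at least 50.7-fold higher against the floor of 3 reads (lower limit of the two-sided interval 40.7, exact binomial test, adjusted p = 5.75e-44). At chromosome 11 position 111758502 there were 361 reads in Q111 and 6 in Q7, a 53.9-fold difference (26.5 to 159.8). The event at chromosome 19 position 51019699 had 282.3 reads in Q111 and 2 in Q7, a 109.6-fold ratio with an interval of 37.5 to 1133. In the other direction, 488 reads in Q7 stood against 7 in Q111 at chromosome 19 position 25536717, a 67.2-fold difference (34.7 to 180.0, exact binomial test, adjusted p = 1.27e-133). At chromosome 8 position 14732368 there were 285.9 reads in Q7 and 3 in Q111, an 84.5-fold ratio (33.3 to 480.1). At chromosome 3 position 101265974 there were 129.9 reads in Q7 and 0 in Q111, at least 44.7-fold higher in Q7 against the same floor (lower interval limit 35.9). Chromosome 17 gave 3 of the 10 events higher in Q7, at positions 72293525, 80654656 and 80654774, the last 2 being 118 bp apart, and 2 of the 10 higher in Q111, at positions 16725981 and 84284501.

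The FRA2 events with the most reads were of another kind. Events at chromosome 8 position 70681285 (936 reads in Q7 and 1008 in Q111) and chromosome 13 position 45719420 (865.9 and 831) differed by 1.04-fold and 1.076-fold, with intervals that include 1. The event at chromosome 15 position 73749843 had 748.8 reads in Q7 and 1078.6 in Q111, a 1.39-fold difference (1.27 to 1.53) below the fold limit. Events at chromosome 11 positions 3053864 and 3086860 were 7.49-fold and 7.86-fold higher in Q111, and both also carried many control reads (135.1 and 106.8 in Q7, against a mean of 4.30 over FRA2 events). With control reads subtracted their log2 folds went from 2.91 and 2.97 to 3.35 and 4.22, and whether they lie in repeats that mm9 holds in too few copies was not checked.

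The balance of FRA2 calls depended on the scaling. With libraries scaled by control reads, which moves the median log2 fold of all FRA2 events to -0.36, 35.0% of calls were higher in Q111 (10585, with 19670 higher in Q7), against 52.2% with the median scaling. With an assumed dispersion of 0.05 in each library, in place of counting error alone, 16897 of the 28797 FRA2 calls were made. Subtracting control reads moved the folds of 19 of the 31 named FRA2 events, shared events included, by over 1.5 times.

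**Figure D1:**
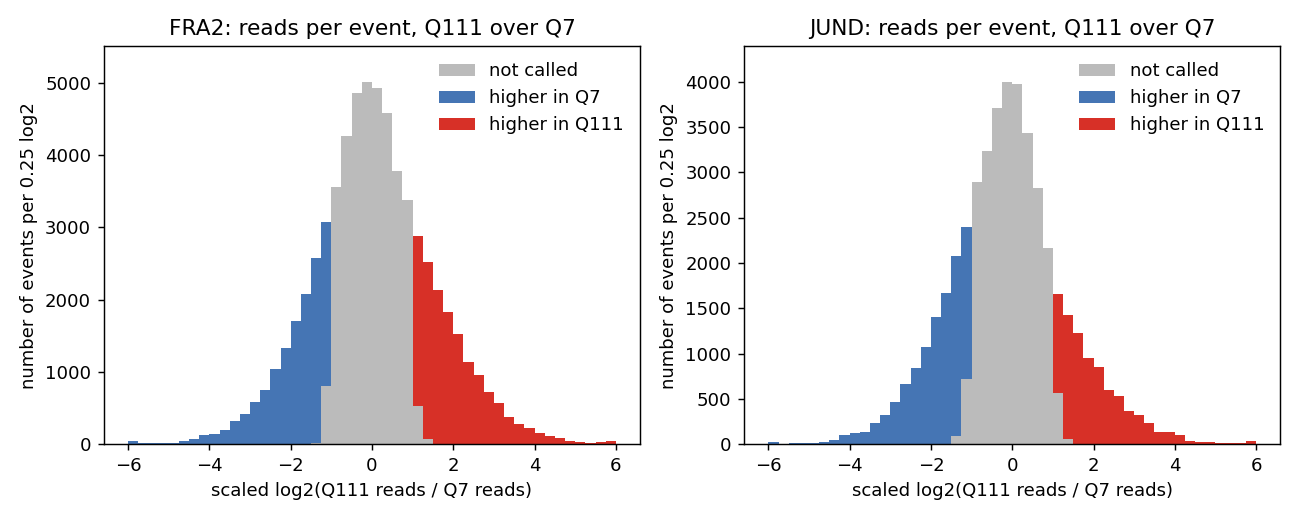
Histograms of the log2 ratio of Q111 to Q7 reads per event for FRA2 (left) and JUND (right), in bins of 0.25, with values beyond -6 and 6 placed in the end bins. Bars are stacked by call (grey, not called; blue, higher in Q7; red, higher in Q111). FRA2 has 15042 events higher in Q111 and 13755 higher in Q7, and JUND has 8091 and 10835.

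The same comparison was made for JUND. JUND reads were higher in Q7 at 10835 events (23.3%, 22.9 to 23.6%) and higher in Q111 at 8091 events (17.4%, 17.03 to 17.7%), and 27657 events (59.4%) were not called. The median called event differed 3.40-fold where higher in Q7 and 3.59-fold where higher in Q111. Of these events, 13.5% (higher in Q7) and 11.7% (higher in Q111) were marked present in both lines. Of the 17305 events present in both lines, 86.1% were not called. Over all JUND events the median log2 fold was -0.13 (-0.14 to -0.12). The share of JUND calls higher in Q111 was 42.8%, and it depended on the scaling. Scaling by read totals gave 48.6% (9058 higher in Q111 and 9562 higher in Q7) with a median of all events of -0.02, and unscaled reads gave 46.4% with a median of -0.06. Scaling by control reads gave 16.8% (4037 and 20023) with a median of -0.79. With an assumed dispersion of 0.05, JUND had 9863 calls in place of 18926.

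The JUND events with the most extreme intervals lay partly at the same places as those of FRA2. At chromosome 19 position 25536722 there were 200 JUND reads in Q7 and 2 in Q111, an 84.3-fold ratio (28.7 to 874.1). At chromosome 8 position 14732377 there were 208.1 reads in Q7 and 5 in Q111, a 39.9-fold difference (18.4 to 136.1). At chromosome 17 position 6180584 there were 122 reads in Q7 and 1 in Q111, an 85.9-fold ratio (22.6 to 5107). Of the 10 events higher in Q111, 3 lay on chromosome 15, at positions 20572675, 32679946 and 33180767, and another 3 on chromosome 11, at positions 110742653, 111741589 and 111758523. The event at chromosome 15 position 32679946 had 206 reads in Q111 and 4 in Q7, a 43.7-fold difference (18.8 to 181.5). Scaling by control reads shifts every JUND log2 fold by 0.66 towards Q7, at this event from 5.45 to 4.79, and subtracting control reads moved it to 6.59. At chromosome 11 position 110742653 there were 118.2 reads in Q111 and 0.5 in Q7, which rounds to 0, at least 37.4-fold higher against the floor of 3 reads (lower interval limit 29.95).

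At 2 of the JUND sites taken by the rule, adjacent positions were listed as separate events. On chromosome 10, position 67248439 had 189.9 reads in Q7 and 0.1 in Q111, and position 67248457, 18 bp away, had 3 in Q7 and 209.7 in Q111. On chromosome 3, position 109057143 had 65.7 reads in Q7 and 0.1 in Q111, and position 109057161 had 0.3 and 73.9. With reads of adjacent events summed, their log2 folds were 0.05 and 0.09, and none of these 4 positions was called. The event at chromosome 3 position 21722530 (69 reads in Q7, 0 in Q111) also had a neighbour at 103 bp, with 13 reads in Q7 and 27 in Q111. The JUND events with the most reads on chromosome 15 differed little between the lines: 1.14-fold at position 59312330 and 1.06-fold at position 57738356, with intervals that include 1, and 1.33-fold (1.14 to 1.54) at position 36814607. The 2 remaining, at chromosome 11 positions 3053865 and 3086838, were 4.30-fold and 4.88-fold higher in Q111 and had 123.2 and 114.4 control reads in Q7. With these subtracted their log2 folds went from 2.10 and 2.29 to 3.21 and 5.63, and with scaling by control reads to 1.44 and 1.63, and repeats were not checked here either.

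The deposited present marks divide events by line. FRA2 events were marked present in both lines in 30731 cases (47.6%, 47.2 to 48.0%), in Q7 alone in 17251 cases (26.7%) and in Q111 alone in 16597 cases (25.7%). For JUND the numbers were 17305 (37.1%, 36.7 to 37.6%), 17904 (38.4%) and 11374 (24.4%). Events marked in Q7 alone were not always called different by reads: 6695 of the FRA2 events (38.8%) and 8528 of the JUND events (47.6%) in this class were not called. The latter JUND events had a median of 25 reads in Q7 and 19.8 in Q111, and a mean of 4.33 control reads in Q7 and 10.9 in Q111. Of events marked in Q111 alone, 4861 FRA2 events (29.3%) and 4230 JUND events (37.2%) were not called. Those JUND events had a mean of 4.26 control reads in Q7 and 4.57 in Q111. Over all JUND events the mean control was 4.32 reads in Q7 and 7.19 in Q111.

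FRA2 and JUND occupied many of the same positions. A JUND event lay within 100 bp of 35715 FRA2 events (55.3%, 54.9 to 55.7%), against at most 0.87% after random displacement, at a median distance of 15 bp. Conversely, 35218 JUND events (75.6%, 75.2 to 76.0%) had a FRA2 event within 100 bp. The share depended on the number of reads. Of 4 equal groups of FRA2 events ranked by reads, the lowest (median 35 reads) had a share of 19.5% and the highest (median 200 reads) 96.8%. FRA2 events higher in Q111 had a JUND event nearby in 47.4% of cases (46.6 to 48.2%), those higher in Q7 in 55.0% (54.2 to 55.9%) and those not called in 58.8% (58.2 to 59.3%). These classes were not matched on reads (medians of 55, 53 and 73 over both lines). More JUND events were marked present in Q7 (35209) than in Q111 (28679), which leaves fewer to lie near FRA2 events higher in Q111. JUND events had a FRA2 event nearby in 78.0% (higher in Q111), 77.9% (higher in Q7) and 74.0% (not called) of cases.

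At the 35176 paired events, the difference between the lines was shared by FRA2 and JUND. The log2 folds correlated across events with a Pearson r of 0.891 and a Spearman rho of 0.894. Events are not independent replicates, and no p is attached. Of 11413 pairs called in both tables, 11409 had the same direction. The sign of the fold was the same at 84.8% of all pairs and at 71.3% of pairs called for neither protein. FRA2 and JUND were both higher in Q111 at 5295 pairs, where independent lists would share 1261.8, and both higher in Q7 at 6114 pairs, where independent lists would share 1791.1. Among pairs called for neither protein the Pearson r was 0.561.

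The shared events with the farthest intervals were again on chromosomes 4, 11 and 15 for Q111. At chromosome 4, FRA2 at position 12235673 had 260 reads in Q111 and 5 in Q7, and JUND at position 12235683 had 102 and 1. At chromosome 11 position 111741574 FRA2 was 50.04-fold higher in Q111 (21.6 to 207.9), and JUND 15 bp away was 64.4-fold higher (16.9 to 3832). At chromosome 15 position 20572986 FRA2 was 38.3-fold higher (21.4 to 78.0). Shared events higher in Q7 were found at chromosome 9 position 47398192, with 81.7 FRA2 reads in Q7 and 0 in Q111, at chromosome 5 position 29360358, with 149.5 and 4.3, and at chromosome 17 position 6180597, with 272.9 and 11. The 2 remaining were the sites on chromosomes 8 and 19 named above.

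**Figure D2:**
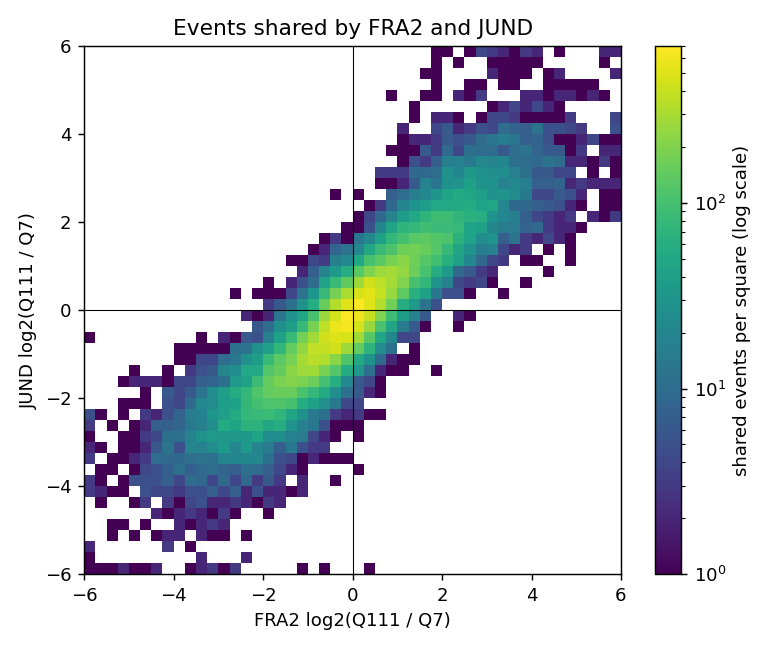
Number of paired events by FRA2 log2 ratio (horizontal axis) and JUND log2 ratio (vertical axis) of Q111 to Q7 reads, in squares of 0.25 with a logarithmic colour scale and values beyond -6 and 6 placed in the outermost squares. The 35176 pairs lie along the diagonal (Pearson r 0.891).

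The FRA2 and JUND differences were themselves compared at each pair. They differed at 76 of 35176 pairs (exact test, Benjamini-Hochberg adjusted p below 0.05), with FRA2 shifted further towards Q111 at 57 and JUND at 19. Before adjustment the same test gave p below 0.05 at 2928 pairs. The other pairs are not shown to be equal, since the median listed event held 64 FRA2 or 54 JUND reads over both lines. The 76 include pairs with the JUND positions 67248439 (chromosome 10) and 109057143 (chromosome 3), which were not called once adjacent events were merged. The test used unscaled reads and does not correct for a shift of a whole table. Unscaled, the median log2 ratio of all events was 0.047 for FRA2 and -0.060 for JUND. Over events present in both lines it was 0.046 for FRA2 and 0.072 for JUND. At 2 of the 76 pairs the calls were opposite. At chromosome 12 position 83924139 FRA2 had 17.3 reads in Q7 and 65.1 in Q111, and JUND at position 83924094 had 40 in Q7 and 16 in Q111. At chromosome 15 position 90170672 FRA2 had 40 reads in Q7 and 102 in Q111, while JUND had 59 and 30. These positions lie outside the rule for named events and were chosen after their values were seen.

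SOX2 binding in Q7 was compared with the AP-1 positions of both lines, events marked present in Q111 alone included. A FRA2 or JUND event lay within 100 bp of 18466 of the 26433 SOX2 events (69.9%, 69.3 to 70.4%), against at most 1.58% after random displacement, and within 1 kb of 86.4%. The displacement does not show what share a protein unrelated to AP-1 would have. JUND was near 61.9% of SOX2 events, FRA2 near 56.4%, and both near 48.5%. The median distance from SOX2 to the matched FRA2 or JUND event was 34 bp. Of 4 equal groups of SOX2 events ranked by reads, the lowest had a share of 55.8% and the highest 84.3%.

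The SOX2 event with the most reads, at chromosome 15 position 64196010, had 899.8 reads, with JUND 143 bp away and FRA2 171 bp away, neither called different between the lines. At chromosome 3 position 19857020, with 515.7 SOX2 reads, FRA2 lay 8 bp away. At chromosome 15 position 71533704 (494 SOX2 reads) the FRA2 event 7 bp away had 876.3 reads in Q7 and 671.7 in Q111. The events at chromosome 14 position 46792765 and chromosome 10 position 85563357 had AP-1 neighbours called higher in Q7, with log2 folds of -2.63 (FRA2) and -2.71 (JUND) for the former and -1.12 and -1.30 for the latter. The remaining strong SOX2 events at chromosome 3 position 40998976, chromosome 15 position 58311993 and chromosome 10 position 121341334 had neighbours that were not called. Those at chromosome 17 positions 39980343 and 39985205 held 189 and 173.7 control reads, against a mean of 4.31, and whether they lie in such repeats was not checked.

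FRA2 and JUND events near SOX2 events had fewer reads in Q111 than the remaining events, relative to Q7. The 23050 FRA2 events within 1 kb of a SOX2 event had a median log2 fold of -0.50, against 0.42 for the 41529 others, a difference of -0.92 (-0.94 to -0.90). Random sets matched on total reads gave -0.05 to 0.04. For JUND the medians were -0.50 over the 23451 events near SOX2 and 0.34 over the others, a difference of -0.83 (-0.86 to -0.81). Among FRA2 events higher in Q111, 3.56% (3.28 to 3.87%) had a SOX2 event within 100 bp, against 38.0% (37.2 to 38.8%) of those higher in Q7 and 26.6% of those not called. For JUND the shares were 7.27%, 53.0% and 36.6%. SOX2 was mapped in Q7 alone. Within bins of Q7 reads the difference near SOX2 was -0.38 (-0.40 to -0.35) for FRA2 and -0.23 (-0.26 to -0.20) for JUND, and over events present in both lines -0.24 (-0.26 to -0.21) for FRA2 and -0.12 (-0.16 to -0.07) for JUND. Q7 reads are part of the fold and the second set leaves out events with large folds, so both restrictions can shrink the difference by construction.

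**Figure D3:**
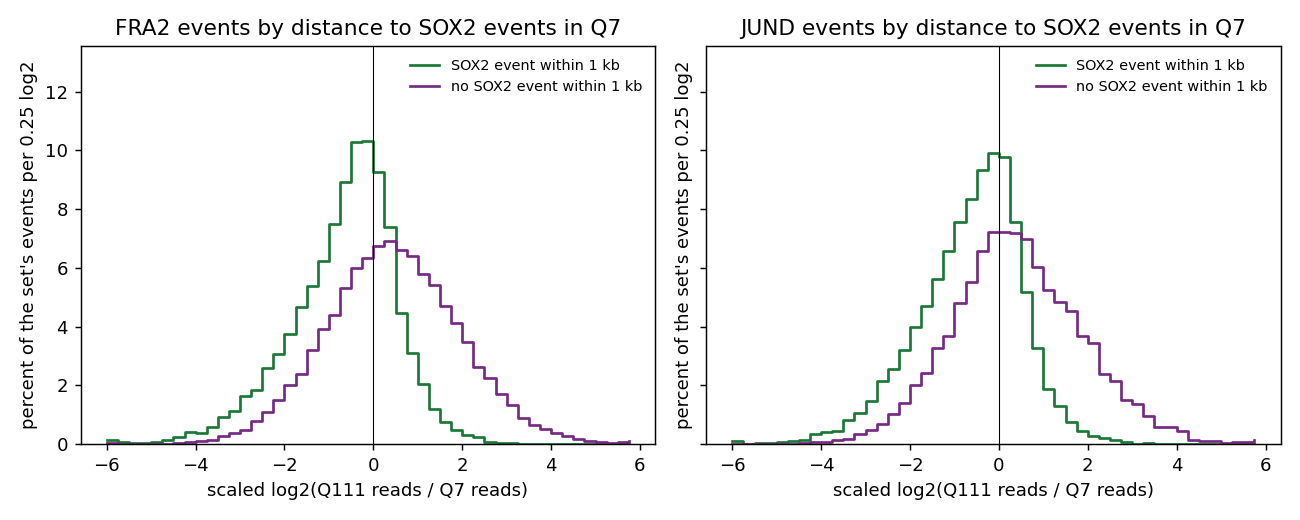
Distribution of log2 ratios of Q111 to Q7 reads for FRA2 (left) and JUND (right) events with (green) and without (purple) a SOX2 event within 1 kb, as percent of each set per bin of 0.25, with values beyond -6 and 6 in the end bins. The FRA2 medians are -0.50 and 0.42, and the JUND medians -0.50 and 0.34. SOX2 was mapped in Q7 alone.

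The shift between the lines differed by chromosome. Chromosome 17 had the lowest medians, -0.47 (-0.51 to -0.43) over 2551 FRA2 events and -0.67 (-0.72 to -0.60) over 1972 JUND events. On it 759 FRA2 events were higher in Q7 and 375 higher in Q111, and for JUND 696 and 159. Chromosome 19 followed with -0.26 for FRA2 and -0.37 for JUND. Chromosome 14 had the highest medians, 0.34 (0.26 to 0.39) for FRA2 and 0.21 (0.13 to 0.30) for JUND. Control reads at FRA2 events, relative to all chromosomes, had log2 ratios of 0.08 on chromosome 17, 0.01 on chromosome 14, 0.22 on chromosome 11 and -0.34 on chromosome X. Over events marked present in both lines the median of chromosome 17 was -0.25 for FRA2 and -0.26 for JUND. Over the same events chromosome 14 had the highest FRA2 median (0.18), while the highest JUND median was on chromosome 11 (0.19, against 0.11 on chromosome 14).

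**Figure D4:**
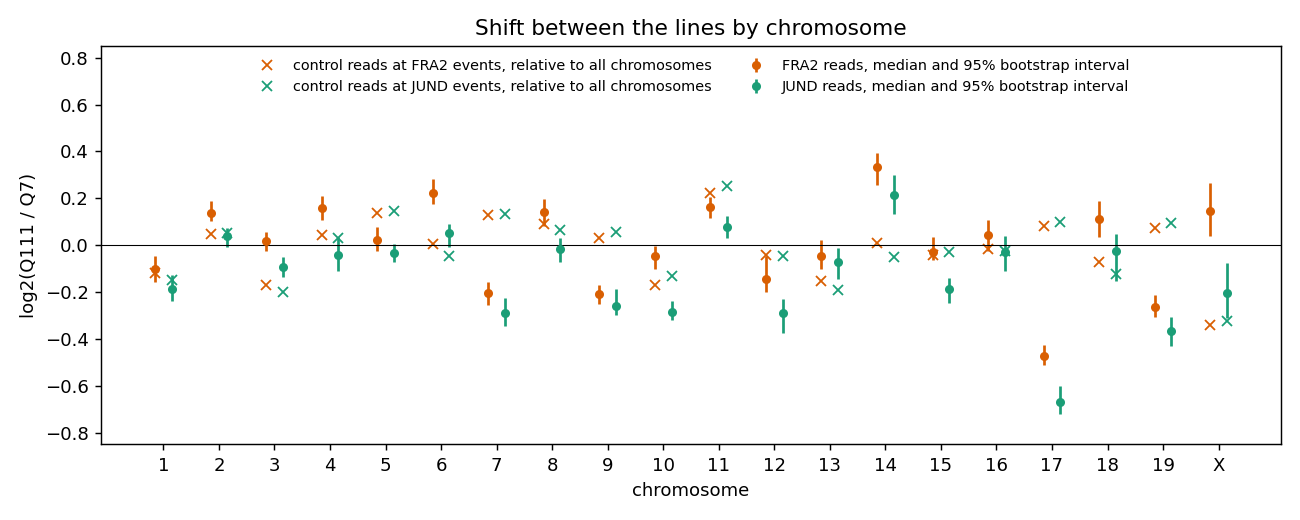
Median log2 ratio of Q111 to Q7 reads per chromosome for FRA2 (orange circles) and JUND (green circles), with 95% bootstrap intervals over events, and the log2 ratio of summed control reads at the same events relative to all chromosomes (crosses). Chromosome 17 lies lowest for both proteins (-0.47 and -0.67), while its control ratios are 0.08 and 0.10. The intervals draw events singly and are too narrow where folds cluster.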

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

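The tests on library yield, on control reads of chromosome 17 and on events present in both lines were chosen after the results they measure had been seen, and the limits for the planned random sets were set after their result. At 76 of 35176 paired events the difference between the lines was not the same for FRA2 and JUND by the exact test of that difference. With reads of events within 100 bp summed, an alternative added after seeing the data, the differences differed at 57 pairs, and the 2 sites with opposite calls on chromosomes 12 and 15 were among them.

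JUND events marked present in Q7 alone outnumbered those in Q111 alone by 1.57 to 1, against 1.04 to 1 for FRA2. The JUND and FRA2 ratios were 1.75 and 1.07 at −log10 q of at least 3, and 1.65 and 0.99 at 5. A lower yield of the Q111 JUND library stays open: the unscaled median log2 ratio was 0.072 (0.061 to 0.086) over events present in both lines, a class that requires high Q111 reads, but -0.06 (-0.07 to -0.05) over all events. The larger Q111 control may account for part of the JUND excess. With the Q7 control used for both lines the JUND ratio dropped from 1.57 to 1.32, between the values set beforehand for a full and for no account. The FRA2 ratio was then 0.97. This swap cannot decide how large the part is. Only sites marked in at least 1 line are listed, so no JUND event could join those in Q111 alone, which went from 11374 to 10837. The swapped Q111 marks were also recomputed, by a comparison that matched the deposited p-value at 85.6% of JUND events in Q111. A difference in JUND binding between the genotypes, or between the lines as clones, also stays open. With 1 line per genotype these cannot be told apart, and without separate replicates neither was tested.

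FRA2 and JUND events near SOX2 events were lower in Q111. A difference in total reads between the sets is argued against, since the lowest of the random FRA2 sets matched on total reads gave -0.055, while the smaller differences within bins of Q7 reads (-0.38 for FRA2 and -0.23 for JUND) do not bear on this, as Q7 reads are part of the fold. A candidate explanation is that SOX2 was mapped in Q7, so that its list selects sites active in Q7: an equally long list of JUND events with the most Q7 reads gave -0.90 (-0.93 to -0.88) for FRA2, beside -0.92 near SOX2, and FRA2 events with the most Q7 reads gave -0.80 (-0.83 to -0.78) for JUND, beside -0.83. Equally long lists by Q111 reads went the other way, with 0.57 for FRA2 (list of JUND events) and 0.62 for JUND (list of FRA2 events). FRA2 and JUND folds correlate (r 0.891), so the sign of the values from all these lists was fixed by the choice of list. They do not show what a list from another protein gives. A part specific to SOX2 cannot be told apart from the selection without SOX2 in Q111.

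FRA2 and JUND events on chromosome 17 were lower in Q111. Fewer copies of the chromosome in Q111 would lower its control reads by 0.3 or more, and at called FRA2 events these were 0.092 (0.026 to 0.159) higher on the log2 scale, relative to all chromosomes. Part of this rise can follow from the mix of calls. Mean control reads in Q7 and Q111 were 4.47 and 5.89 at FRA2 events higher in Q7, which are more frequent on chromosome 17, and 3.99 and 4.12 at those higher in Q111. At FRA2 events not called the value was 0.072 (0.005 to 0.143). Events marked in 1 line only are not the whole of the chromosome 17 shift, since FRA2 events present in both lines had a median of -0.25 (-0.28 to -0.20). That interval draws events singly and is too narrow where folds cluster. A difference between the genotypes or between the lines as clones stays open and was not tested. As the control library is not named in the headers, the first test assumes that it reflects copy number.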

How the results depend on the processing

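The scaling without any factor, by read totals and by control reads, the medians per chromosome, the subtraction of control reads, the fold limit of 1.5 and the 2 exclusions added after seeing the data (merged events, events with 40 or more control reads) left the total numbers of FRA2 and JUND calls within 1.5 times. By direction, scaling by control reads moved JUND calls higher in Q111 from 8091 to 4037 and those higher in Q7 from 10835 to 20023, and FRA2 calls from 15042 to 10585 and from 13755 to 19670. The read minimum of 0 removed no event and tests nothing. Among settings that keep events separate, none turned the direction of a call. Apart from control subtraction, they moved folds too little to turn one, so this tests little. With scaling by control reads, 24340 of 28797 FRA2 calls and 14872 of 18926 JUND calls were kept. Present marks at −log10 q of at least 3, and with the Q7 control for both lines (added after seeing the data), also gave counts within 1.5 times. Counts moved further with a minimum of 50 reads (FRA2 15770, JUND 8395), a dispersion of 0.05 (FRA2 16897, JUND 9863), a fold of at least 4 (FRA2 11460, JUND 7554) and, for JUND, −log10 q of at least 5 (11275). The minimum and the q limit test fewer events, the fold limit is higher, and the dispersion assumes a wider spread at the same events. At −log10 q of at least 5, 19988 FRA2 events were present in both lines, and JUND had 7929 in both, 10849 in Q7 alone and 6558 in Q111 alone. The share of FRA2 events with JUND nearby was 39.2% within 25 bp, 49.99% within 50 bp, 58.9% within 250 bp and 49.0% with −log10 q of at least 5. For SOX2 it was 51.7% within 50 bp, 80.3% within 250 bp and 77.1% with −log10 q of at least 5. The FRA2 and JUND correlation was 0.900 with a minimum of 50 reads. Near SOX2 the difference was -0.88 (FRA2) and -0.80 (JUND) within 250 bp and -0.87 (JUND) within 10 kb. Within bins of Q7 reads, added after seeing the data, it was -0.38 (FRA2) and -0.23 (JUND), and over events present in both lines -0.24 and -0.12, restrictions that can shrink it by construction. Over events present in both lines, also added, chromosomes 14, 17 and 19 had FRA2 medians of 0.18, -0.25 and -0.16 and JUND medians of 0.11, -0.26 and -0.14. Where no construction is named, the cause was not tested. Of the 59 named events, which the rule chose for extreme folds or many reads, 4 lost their call when adjacent events were merged. None changed its call under the planned scalings, control subtraction or dispersion, but events so chosen do not show that other calls hold. Their folds moved by over 1.5 times at 19 of 31 FRA2 and 22 of 28 JUND events with control reads subtracted, at all 28 JUND events with scaling by control reads (0.66 on the log2 scale), and with merging at 1 FRA2 event (chromosome 17 position 84284501, log2 7.07 to 4.40) and 4 JUND events. The gene lists, genomic location and motif alternatives were not run. At the observed depth, simulated 4-fold changes were recovered in 78% of FRA2 and 63% of JUND events. This simulation had 200 changed events and counting error alone, so these shares are not those of the real comparison. Depth was not varied. No leave-one-out or paired fit was possible because each group is 1 pooled sample.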

Other observations

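The windows and neighbouring events described here were examined after seeing the data. Folds were summarised along chromosomes. In windows of 5 Mb with at least 20 events in both tables, 464 in all, the median log2 folds of FRA2 and JUND had a Spearman rho of 0.829 across windows, which also reflects their correlation at paired events (r 0.891). Window medians had an SD of 0.497 for FRA2 (490 windows with at least 20 FRA2 events) and 0.447 for JUND (464), against at most 0.256 and 0.265 in 100 shuffles of folds among the events of each chromosome. With 1 event kept per 10 kb the SDs were 0.515 (482 windows) and 0.460 (456), against at most 0.280 and 0.297. The windows named next were ranked by the smaller of their FRA2 and JUND medians in absolute size, where both had the same sign. Agreement of FRA2 and JUND there was required by this choice, which was made after their values were seen. The window with the strongest shift towards Q111 was chromosome 6 from 10 to 15 Mb, with a median of 2.11 over 60 FRA2 events and 2.43 over 40 JUND events. There 45 FRA2 events were called higher in Q111 and 1 higher in Q7. Chromosome 4 from 70 to 75 Mb (1.68 and 1.56) and chromosome 8 from 55 to 60 Mb (1.63 and 1.35) followed. The strongest shifts towards Q7 were on chromosome 14 from 115 to 120 Mb (-1.45 and -1.36) and chromosome 9 from 90 to 95 Mb (-1.03 and -1.03), though the JUND median was lower on chromosome 1 from 20 to 25 Mb (-1.09, FRA2 -0.96). Control reads at FRA2 events of the chromosome 6 window, relative to the genome, had a log2 ratio of -1.26, with -0.78 and -0.64 in the windows of chromosomes 4 and 8, -0.08 and -0.14 in those of chromosomes 14 and 9, and -0.62 in that of chromosome 1. Across windows the FRA2 medians and control ratios had a Spearman rho of -0.19 and the JUND medians one of -0.01. Of the 19 windows of chromosome 17, 17 had a FRA2 median below 0.

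Control reads on chromosome X were lower in Q111 at called FRA2 events, by a log2 ratio of -0.36 (-0.49 to -0.24) relative to all chromosomes, and on chromosome 11 they were higher, at 0.18 (0.12 to 0.25). On chromosome X the FRA2 median was 0.14 over all events and -0.02 over events present in both lines, and the JUND median was -0.20 (-0.31 to -0.08). On chromosome 11 the FRA2 and JUND medians were 0.16 and 0.08.

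Adjacent events within 100 bp of each other were rare, 190 neighbouring pairs in the FRA2 table and 7 in the JUND table. Opposite calls occurred in 3 of the FRA2 pairs and 2 of the JUND pairs, and all of them were not called after merging.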
